A study of Mus musculus with 15 samples.

How the data were processed

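Gene expression was measured by RNA sequencing in 15 libraries of mouse embryonic stem cells that had been differentiated and sorted. Per the labels' protocols, total RNA of the sorted cells was amplified with a Nugen kit and made into libraries after the Illumina protocol. The sort gates, the culture days and the strandedness of the libraries are not given in the sources used here. The deposited values are raw read counts per gene symbol, whole numbers with 1 column per library. Per the submitters' processing notes, the authors' tools were STAR 2.4.0 and HTSeq 0.6.1 with the mm10 genome, and what each tool did, the gene annotation, the strand setting and any filter are not given in the sources used here. Values of overlapping or antisense genes (such as Igf2r with Airn, and Six3os1) and of near-identical families (globins, histones) are therefore uncertain.

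The table had 24061 lines. In 27 of them a calendar date stood where a gene symbol belongs, as happens when spreadsheet programs read symbols as dates. These lines were left out, and no attempt was made to recover the genes behind them. Of the 24034 lines kept, 23614 matched a gene of the GENCODE M21 annotation (assembly GRCm38, which is mm10), 22682 of them directly and 932 through an older symbol. This annotation gave coordinates, GC content and transcript length. Library totals were 9705729 to 16375835 counts. A count of 0 was taken to allow up to 3 counts in that library, which covers counting error only.

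Samples were grouped by their labels into 5 groups of 3 libraries. The main analysis used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr, which left 13662, libraries were scaled with TMM factors, and 1 robust quasi-likelihood model with a mean per group was fitted to all 15 libraries, so that all groups shared 1 estimate of the spread. Adjusted p values are Benjamini-Hochberg values from the edgeR quasi-likelihood test unless another tool is named, and the threshold was 0.05. Standard errors (SE) of log2 fold changes are those that give the quasi-likelihood statistic. Levels are CPM, edgeR's unit of counts at a common library size, after TMM scaling, given as mean ± SD over the 3 libraries of a group. Log2 differences within pairs of libraries used a prior count of 2. The comparisons were FLK1+ LacZ+ against LacZ− cells, HEI ENG+FDG+ against ENG+FDG− cells, HEI ENG+FDG+ against ENG−FDG+ cells, HEI ENG−FDG+ against ENG+FDG− cells, any difference among the 3 HEI fractions, the mean of the HEI groups against the mean of the FLK1+ groups, and the difference between the HEI FDG effect and the FLK1+ LacZ effect.

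Gene lists were tested with camera, which asks whether a list's genes lie higher or lower than other genes, with a preset correlation of 0.01 between genes. Alternatives were camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way. Adjustment was over the lists within a comparison. The 24 lists were endothelial, early haematopoietic, erythroid, megakaryocyte, myeloid, cardiac, smooth muscle and mesenchyme, primitive streak and nascent mesoderm, paraxial and lateral mesoderm, pluripotency, endoderm, neural and ectoderm, Notch pathway, BMP and TGF-beta pathway, LRP2 and endocytic receptors, retinoic acid pathway, Hedgehog pathway, Wnt pathway, Hox and Cdx, cell cycle, hypoxia and glycolysis, immediate early and stress, mitochondrially encoded, and replication-dependent histones. Counts "adjusted over the list alone" apply the same adjustment to a list's members only.

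The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. For the FLK1+, FDG, ENG and stage comparisons the rule takes the 6 largest rises and the 6 largest falls among genes past the threshold whose groups do not overlap and whose higher group averages at least 10 CPM, leaving out unnamed gene models. It adds the fixed genes Eng, Kdr, Lrp2, Tek, Kit, Itga2b, Pecam1, Cdh5, Runx1, Gfi1, Gata2 and Tal1, and up to 4 members past the threshold of each list discussed, or the 2 with the highest level where none passed. For the other comparisons it takes 3 rises and 3 falls with Eng and Lrp2. Lrp2 is in the study's title and was thus chosen by the study on these samples. Eng and Kdr encode sort markers that the labels name, and Eng is also the locus of the reporter's elements and served as a check of the labels. Tek, Kit and Itga2b encode surface markers by which the study's summary describes cells targeted by the −8 kb enhancer. Genes found by the same rule under the replicate block, or in replicates 2 and 3, were chosen after their values were seen and are named as such.

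Alternatives set before were RLE size factors, no filter on low counts, a filter of at least 5 CPM in 3 libraries, a fit of only the groups compared, a test against a fold of 1.5, DESeq2 1.42.0, each library left out in turn, and the replicate number as a block. The numbers were then checked for pairing by the correlation across 9447 genes of the libraries' deviations from their group means. Same-numbered libraries correlated at 0.821 to 0.885 in FLK1+ cells and at 0.730 to 0.947 in HEI cells. Replicate 2 of a group with replicate 3 of another gave 0.752 to 0.813 and 0.690 to 0.847, nearly as high, since replicate 1 stood apart from both. The difference of replicate 2 minus 3 correlated between groups at only 0.187 in FLK1+ and 0.143 to 0.263 in HEI cells. The numbers were taken to pair the samples because every same-numbered correlation was over 0.1, and the evidence beyond replicate 1 is weak. The pairing comes from the data and not from the labels. Because the replicate 1 libraries stood apart, a fit of replicates 2 and 3 only, with and without the block, was added after the data had been seen.

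The analysis was tested on counts drawn for the real genes with 200 genes changed per comparison, 100 at each of 2 folds. Their means and spread came from the fit with the replicate block. Same-numbered libraries of the groups compared shared a mean before the changes, so pairing by number was built in. The runs thus cannot show that the block suits the real samples. The edgeR test recovered 1% of the 2-fold and 31% of the 4-fold changes for the FLK1+ LacZ comparison, 0% and 32% for the HEI FDG comparison, and 2% and 46% for the HEI ENG comparison. With the replicate block it recovered 66% and 94%, 63% and 92%, and 68% and 96% in the same order, with 6, 14 and 14 false calls against 0 without it. DESeq2 recovered 17% and 58%, 20% and 71%, and 22% and 72%. From replicates 2 and 3 edgeR recovered 45% and 86%, 39% and 85%, and 49% and 85%, with 8, 5 and 9 false calls. The real spread within these replicates was smaller than the one drawn. No recovered gene had the wrong sign. The runs of all replicates covered 13480 to 13533 genes. For other groupings of the libraries, all 10 splits of 3 against 3 and, with the block, the 36 splits of the HEI libraries with 1 of each replicate number per group were refitted, and 100 splits were drawn with a fixed seed for each of the larger designs. For the weighing of explanations, GC content and transcript length entered as splines with 5 degrees of freedom, and matched random lists were drawn 10000 times. Results that need an item withheld for evaluation are not reported here.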

Results

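The 15 libraries came from mouse embryonic stem cells carrying LacZ, which encodes bacterial beta-galactosidase, under control elements of Endoglin (Eng), a TGF-beta co-receptor of endothelial and early blood-forming cells. Cells with an active reporter are labelled LacZ+, or FDG+ after FDG, a substrate that turns fluorescent when the enzyme splits it. From a line that joined the Eng promoter to enhancers at −8, +7 and +9 kb, cells positive for FLK1 (the VEGF receptor encoded by Kdr) were sorted into LacZ− and LacZ+ fractions. From a line with the promoter and the −8 kb enhancer, fractions that the labels call HEI were sorted as ENG+FDG−, ENG+FDG+ and ENG−FDG+, ENG being the Endoglin protein. Each of the 5 groups had 3 libraries, numbered 1 to 3. The labels do not name separate cultures, so the p values measure the spread between these samples.

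Library totals ran from 9705729 to 16375835 counts, and 13975 to 17088 genes had at least 1 read. The 5 replicate 1 libraries stood apart from the other 10. They held at least 12218593 counts each against at most 11785528. Ribosomal precursor RNA (Rn45s) took 1.40% to 3.56% of their counts against 0.522% to 0.782%. Of 13662 genes tested with edgeR, 9740 (71.3%) differed between replicate 1 and replicates 2 and 3, 5339 of them higher and 4401 lower in replicate 1. The biological coefficient of variation was 0.477 with group means alone, 0.182 with the replicate number as a block and 0.076 within replicates 2 and 3. Values for replicate 1 alone and for replicates 2 and 3, an alternative chosen after the data had been seen, are therefore given for a part of the results below. Within a group the log2 CPM of replicates 2 and 3 correlated at 0.987 to 0.990. Whether these replicates are separate cultures is not given. The p values and counts of genes from fits of them alone may thus not measure the spread between cultures.

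**Figure D1:**
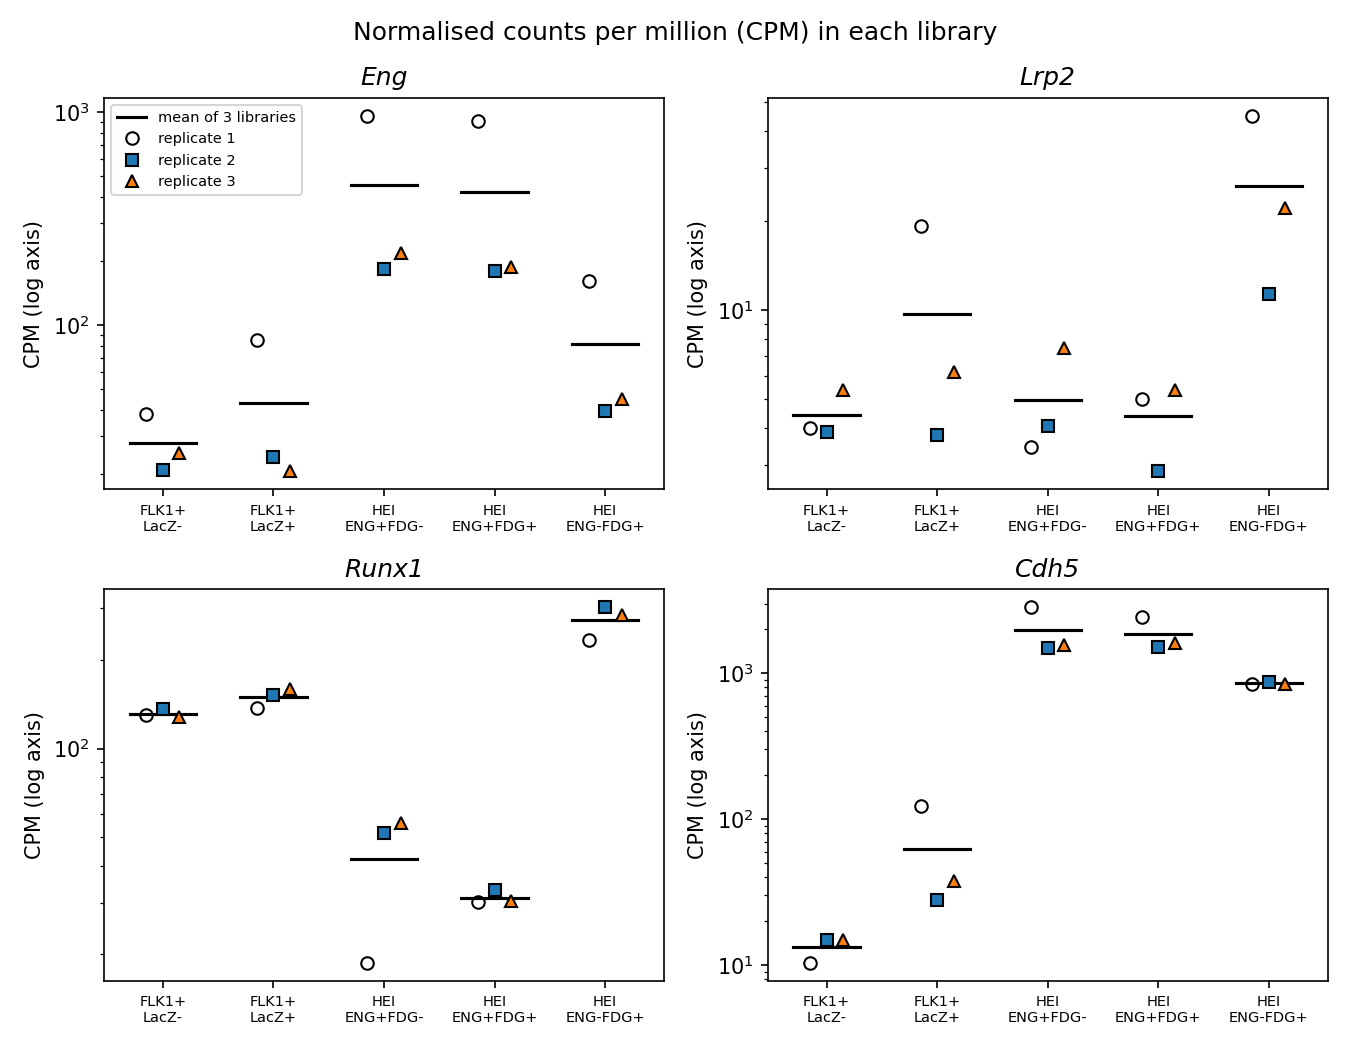
CPM of Eng, Lrp2, Runx1 and Cdh5 on a log axis in each library of the 5 groups, with replicate 1 as open circles, replicate 2 as filled squares, replicate 3 as filled triangles and a line at the mean of 3. Runx1 lay between 234 and 303 CPM in the ENG−FDG+ libraries and between 30.3 and 33.0 CPM in the ENG+FDG+ libraries, and replicate 1 held the highest Eng value of every group.

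The first comparison asked which transcripts accompany activity of the 3-enhancer reporter in FLK1+ mesoderm. Eng, a check of the labels, stood at 43.2 ± 36.4 CPM in LacZ+ and 28.1 ± 9.17 CPM in LacZ− cells (mean ± SD, n = 3 each). The log2 difference of 0.63 ± 0.86 (SE) did not pass the edgeR test (adjusted p = 1) and was positive in 2 of 3 same-numbered pairs. In replicates 2 and 3 the difference was −0.05 ± 0.13 log2, so these replicates did not show more Eng in LacZ+ cells. Endothelial genes as a list rose in LacZ+ cells, with 23 of 25 members higher (camera adjusted p = 2.8e-26; adjusted p = 0.0323 with an estimated correlation, 0.351 with that and the replicate block, and 0.291 with fry). None passed the threshold over all genes, and Cdh5, Pecam1, Tie1 and Cldn5 (4 genes) passed it adjusted over the list alone. Among them, Cdh5, the junction protein VE-cadherin, stood at 62.9 ± 52.5 against 13.4 ± 2.61 CPM, and Pecam1, another adhesion protein of the endothelium, at 27.5 ± 17.2 against 7.37 ± 2.31 CPM, both higher in 3 of 3 pairs. Early haematopoietic genes rose as a list as well, with 19 of 21 members higher (camera adjusted p = 9.5e-10; adjusted p = 0.0323 with an estimated correlation, 0.351 with that and the replicate block, and 0.291 with fry). Mixl1 and Tdgf1, a homeobox gene and a Nodal co-receptor of the primitive streak, were lower in 3 of 3 pairs.

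Within the early haematopoietic list no gene passed the threshold alone or adjusted over the list alone without the block. With it, 22 endothelial and 8 early haematopoietic genes rose adjusted over the list alone, and none over all genes. Runx1 and Tal1, transcription factors needed to form blood, differed by 0.18 ± 0.31 and 0.34 ± 0.47 on the log2 scale. All 8 megakaryocyte genes tested were higher in LacZ+ cells (camera adjusted p = 1.8e-06; adjusted p = 0.129 with an estimated correlation), among them the integrin genes Itgb3 at 0.93 ± 0.89 and Itga2b at 0.88 ± 0.45 log2. Without 1 library Itgb3 ranged from 0.024 to 1.268 and Itga2b from 0.213 to 1.123. The median of the 8 genes was 1.48 log2 in replicate 1 and 0.104 and 0.20 in replicates 2 and 3. The myeloid list (8 of 9 higher, camera adjusted p = 0.00441) and the Hox and Cdx list (13 of 17 higher, camera adjusted p = 0.0186) rose too, with adjusted p = 0.349 and 0.354 with an estimated correlation. Adjusted over the list alone 1 myeloid gene, Mpo, and no Hox or Cdx gene passed. Their most abundant members were Laptm5 at 1.57 ± 0.61, Mrc1 at 0.48 ± 0.46, Hoxb5 at 0.98 ± 0.49 and Hoxb3 at 0.43 ± 0.78 log2. Without 1 library they ranged from 0.414 to 1.937, 0.07 to 0.75, 0.565 to 1.668 and 0.003 to 0.892, in this order. The myeloid median was 1.07 log2 in replicate 1 and 0.365 and −0.082 in replicates 2 and 3. The primitive streak list fell, with 15 of 18 members lower (camera adjusted p = 0.00104; adjusted p = 0.381 with an estimated correlation, and 0.0311 with that and the replicate block). So did the paraxial and lateral mesoderm list, with 11 of 17 lower (camera adjusted p = 0.0045; adjusted p = 0.349 with an estimated correlation). Mixl1 differed by −0.62 ± 0.89 and Tdgf1 by −0.94 ± 1.01 log2, whereas Hand1 and Rspo3, the most abundant genes of the last list, differed by 0.14 ± 0.95 and 0.07 ± 0.47. Lrp2, which encodes the endocytic receptor megalin, had 9.71 ± 8.27 CPM in LacZ+ and 4.42 ± 0.833 CPM in LacZ− cells, a difference of 1.14 ± 0.61 log2 that did not pass the test. Its counts were 300, 38 and 60 in the LacZ+ libraries and 57, 42 and 58 in the LacZ− libraries, so the difference was 2.22 log2 in replicate 1 and 0.09 ± 0.50 in replicates 2 and 3. Of the other fixed genes, Tek, Kit and Itga2b were higher in 3 of 3 pairs by 1.07 ± 0.39, 0.65 ± 0.31 and 0.88 ± 0.45 log2. Gfi1 and Gata2 differed by 0.50 ± 0.58 and 0.23 ± 0.43, and Kdr, the sort marker itself, by −0.12 ± 0.33.

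No single gene of the 13662 passed the threshold with edgeR, with or without the replicate block, and 170 had an unadjusted p under 0.05. DESeq2 called 7 genes, all higher in LacZ+ cells. In replicates 2 and 3 edgeR called 8 genes, 5 higher and 3 lower, and 157 with the block, 104 higher and 53 lower. Genes named from this fit were chosen after their values were seen. Cdh5 rose by 1.12 ± 0.12 log2 (adjusted p = 0.000188) and Ptprb, an endothelial receptor phosphatase, by 0.74 ± 0.11 (adjusted p = 0.0071), against 3.55 and 1.75 in replicate 1. Grb10, an imprinted adaptor of insulin receptor signalling, fell by 1.71 ± 0.17 log2 (adjusted p = 5.0e-05; −1.97 in replicate 1), while Pdcd4 fell by 0.64 ± 0.12 (adjusted p = 0.042) but differed by 0.16 in replicate 1. The median log2 difference of the endothelial list was 2.04 in replicate 1, 0.27 in replicate 2 and 0.47 in replicate 3, and that of the early haematopoietic list was 1.40, 0.01 and 0.31. The endothelial, early haematopoietic and primitive streak lists passed again in replicates 2 and 3 (camera adjusted p = 4.6e-11, 0.0217 and 0.000193; adjusted p = 0.0507, 0.579 and 0.527 with an estimated correlation). The megakaryocyte, myeloid, Hox and Cdx and paraxial lists did not pass there (0.383, 0.310, 0.247 and 0.0624). Without LacZ− replicate 2, edgeR called 1 gene, Gimap4 (3.71 log2, adjusted p = 0.0298), named after its value was seen.

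**Figure D2:**
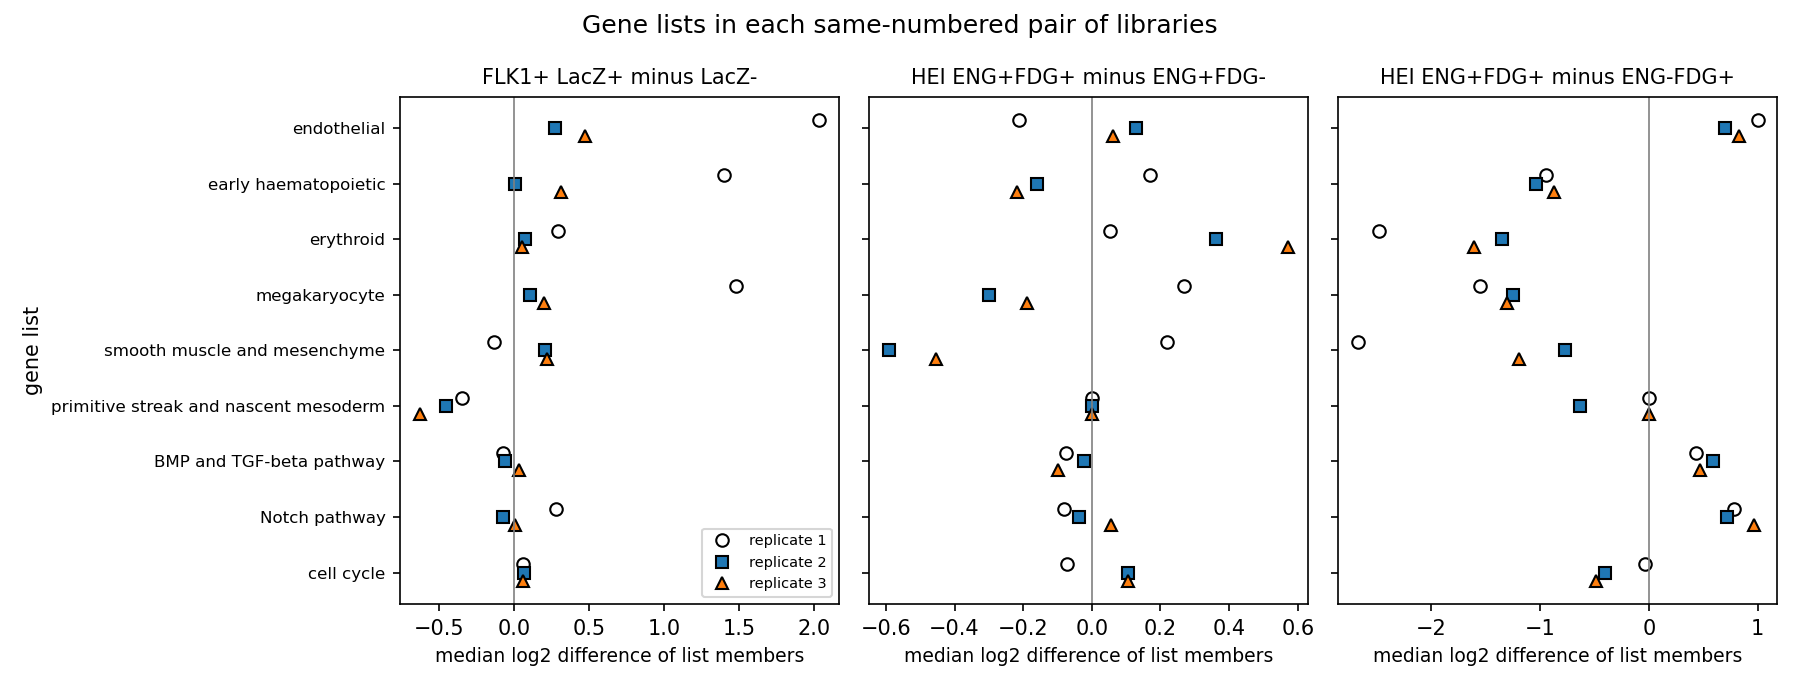
Median log2 difference of the tested members of 9 gene lists in each same-numbered pair of libraries, for FLK1+ LacZ+ against LacZ−, HEI ENG+FDG+ against ENG+FDG− and HEI ENG+FDG+ against ENG−FDG+ cells. The endothelial median of the FLK1+ comparison was 2.04 in replicate 1 and 0.27 and 0.47 in replicates 2 and 3, while that of the last comparison was 0.998, 0.702 and 0.831, on a separate scale per panel.

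Among HEI cells, the ENG comparison set ENG+FDG+ against ENG−FDG+ cells, both with an active −8 kb reporter. Eng, the check of the sort, stood at 424 ± 416 CPM in ENG+FDG+ and 81.8 ± 68.6 CPM in ENG−FDG+ cells (n = 3 each) and was higher in 3 of 3 pairs. The difference of 2.37 ± 0.89 log2 did not pass the edgeR test (adjusted p = 0.372) but did so with the replicate block (2.25 ± 0.20, adjusted p = 0.000131). Without 1 library the unblocked difference ranged from 1.168 to 3.33 log2. Runx1 fell 8.76-fold in ENG+FDG+ cells, to 31.2 ± 1.60 from 273 ± 35.2 CPM (log2 −3.13 ± 0.33, adjusted p = 0.00384, lower in 3 of 3 pairs). Endothelial genes rose as a list and early haematopoietic, erythroid, megakaryocyte and smooth muscle genes fell as lists by camera with its preset correlation. None of these 5 lists passed with an estimated correlation (adjusted p = 0.0662 to 0.246). Clec14a, a surface protein of the endothelium, rose 4.49-fold to 81.9 ± 12.4 CPM, and Slc7a8, an amino acid transporter, fell 23.4-fold to 1.58 ± 0.559 from 37.6 ± 7.31 CPM. Lrp2 was lower in 3 of 3 pairs, at 4.41 ± 1.36 against 26.2 ± 17.2 CPM. The difference was −2.56 ± 0.64 log2 with adjusted p = 0.126, and −2.49 ± 0.48 with adjusted p = 0.00749 with the replicate block. It was −3.13 log2 in replicate 1 and −1.97 ± 0.45 in replicates 2 and 3 (adjusted p = 0.00951).

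By the rule, the 6 largest rises in ENG+FDG+ cells began with Plekhg1 (2.36 ± 0.38 log2, adjusted p = 0.0302), Clec14a (2.17 ± 0.39, adjusted p = 0.0436) and Pdzd2 (1.82 ± 0.30). They were followed by Dock4 (1.66 ± 0.31), the protease gene Ctsh (1.64 ± 0.31) and the receptor phosphatase gene Ptprm (1.60 ± 0.22, adjusted p = 0.0133). The 6 largest falls began with Nrip3 (−5.07 ± 0.85 log2, adjusted p = 0.0426), Slc7a8 (−4.55 ± 0.50, adjusted p = 0.00384) and Reln, a secreted glycoprotein (−4.15 ± 0.71). Next came the cardiac actin gene Actc1 (−3.96 ± 0.73), the matrix protein gene Postn (−3.76 ± 0.68) and the homeobox gene Nkx1-2 (−3.42 ± 0.60). Without 1 library Actc1 ranged from −4.44 to −2.51 log2 and Nkx1-2 from −3.78 to −2.38. The adjusted p values of these 12 genes were 0.00384 to 0.0459. The rule takes only genes whose groups do not overlap, so their same direction in 3 of 3 pairs follows from it and adds no support.

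Of the 25 endothelial genes 24 were higher in ENG+FDG+ cells and none passed alone or adjusted over the list alone (camera adjusted p = 5.6e-08; adjusted p = 0.213 with an estimated correlation). With the block 13 rose and 1 fell. Cdh5 stood at 1847 ± 494 against 852 ± 20.9 CPM and Kdr at 932 ± 142 against 572 ± 146 CPM, of which Kdr rose with the block (0.72 ± 0.11 log2, adjusted p = 0.00234). Eng, whose protein was the sort marker, is a member of the endothelial and the BMP and TGF-beta lists. In this comparison and the third, 1 member of each list is thus tied to the sort itself. The BMP and TGF-beta list rose, with 1 of 23 members past the threshold, or 3 (Id2, Bmp6 and Tgfbr2) adjusted over the list alone (camera adjusted p = 0.000347; adjusted p = 0.107 with an estimated correlation). Id2, the member past it over all genes, is a BMP target that blocks helix-loop-helix factors, and stood at 36.2 ± 2.68 against 12.6 ± 2.0 CPM (1.52 ± 0.27 log2, adjusted p = 0.0436), and 10 rose with the block. The Notch list rose with 12 of 16 members higher, 2 (Efnb2 and Gja5) rising and 1 (Notch2) falling adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.360 with an estimated correlation). Its most abundant members were Efnb2, an arterial ephrin, at 1.02 ± 0.23 log2, and Notch1 at 0.81 ± 0.73, and both rose with the block (adjusted p = 0.000256 and 0.00444).

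Of 21 early haematopoietic genes only Runx1 passed over all genes, 7 fell adjusted over the list alone, and 9 fell and 1 rose with the block (camera adjusted p = 7.4e-08; adjusted p = 0.069 with an estimated correlation). The erythroid list fell, with 7 of 9 members lower and 2 (Gata1 and Hbb-bh1) past the threshold adjusted over the list alone (camera adjusted p = 0.00054; adjusted p = 0.0662 with an estimated correlation). Tfrc, the transferrin receptor, differed by −1.40 ± 0.77 log2 and fell with the block (−1.31 ± 0.10, adjusted p = 5.8e-05), and Slc25a37, a mitochondrial iron importer, differed by 0.03 ± 0.19. The megakaryocyte list fell, with 7 of 8 members lower and Gp1ba, Plek and Nfe2 past the threshold adjusted over the list alone (camera adjusted p = 2.4e-06; adjusted p = 0.107 with an estimated correlation). Itgb3 and Itga2b differed by −2.03 ± 0.90 and −0.50 ± 0.44 log2. The myeloid list fell narrowly (camera adjusted p = 0.0433; adjusted p = 0.437 with an estimated correlation, and 0.113 with the block), with 1 of 9 members (Mpo) past the threshold adjusted over the list alone. Laptm5 differed by −0.82 ± 0.58 and Mrc1 by 0.75 ± 0.42. The smooth muscle and mesenchyme list fell, with 17 of 18 members lower, 5 (Acta2, Pdgfrb, Col1a1, Col1a2 and Postn) past the threshold adjusted over the list alone and 11 with the block (camera adjusted p = 5.4e-08; adjusted p = 0.246 with an estimated correlation). Postn was its member past the threshold over all genes. Without 1 library Acta2 ranged from −4.438 to −0.907 log2, Col1a1 from −5.947 to −1.569 and Postn from −4.194 to −3.197. The cell cycle list fell by little, with all 27 members lower, 5 past the threshold with the block and none without it, also adjusted over the list alone (camera adjusted p = 0.00054; adjusted p = 0.246 with an estimated correlation). Its median was −0.035 log2 in replicate 1 and −0.399 and −0.483 in replicates 2 and 3. Top2a and Mki67 differed by −0.13 ± 0.58 and −0.11 ± 0.31 log2. The histone list missed the threshold (camera adjusted p = 0.0511) and fell with the block (0.00057; adjusted p = 0.490 with an estimated correlation). The other fixed genes did not pass the test. Tek, Pecam1 and Cdh5 were higher by 0.71 ± 0.39, 0.61 ± 0.39 and 1.12 ± 0.48 log2. Kit, Gata2, Tal1 and Gfi1 differed by −0.41 ± 0.31, −0.48 ± 0.43, −1.0 ± 0.47 and −1.62 ± 0.56, and Gfi1 fell with the block (−1.66 ± 0.43, adjusted p = 0.0281).

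With the replicate block, genes found by the same rule and chosen after their values were seen included Robo4, an endothelial guidance receptor (2.63 ± 0.23 log2, adjusted p = 0.00012) and Pdlim3 (3.37 ± 0.23), both higher in ENG+FDG+ cells. Also higher were Notch4 (1.66 ± 0.29) and the receptors of TGF-beta and BMP9, Tgfbr2 (1.49 ± 0.23) and Acvrl1 (1.41 ± 0.20). Lower were Myb, a transcription factor of blood progenitors (−3.84 ± 0.48 log2, adjusted p = 0.000747), Ikzf1 (−2.49 ± 0.26), the erythroid factor Gata1 (−2.96 ± 0.68), the embryonic globin Hbb-bh1 (−2.85 ± 0.32), Acta2 (−2.66 ± 0.42) and Mcm7 (−0.70 ± 0.08).

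EdgeR called 38 genes in this comparison, 19 higher and 19 lower, with 1288 at an unadjusted p under 0.05. All 38 were also called with the block, by DESeq2 and in replicates 2 and 3. The count was 1705 with the block (813 higher, 892 lower), 405 with DESeq2 (214 higher, 191 lower) and 3899 in replicates 2 and 3 (1952 higher, 1947 lower). It was 4, 0 and 3 without ENG+FDG+ replicates 1, 2 and 3, and 34, 21 and 4 without ENG−FDG+ replicates 1, 2 and 3. Runx1, Slc7a8 and the R-spondin receptor gene Lgr5 were in each of the small sets, joined by Prex2 in the first and Pard6b in the last, and the last 3 of these 5 were chosen after their values were seen. Runx1 and Slc7a8 kept their call in 5 of these 6 fits and lost it without ENG+FDG+ replicate 2 (adjusted p = 0.0629), and the other genes that the rule named as past the threshold lost it in 4 to 6 of them.

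The FDG comparison asked what distinguishes ENG+ HEI cells with an active −8 kb reporter from those without, and set ENG+FDG+ against ENG+FDG− cells. Eng stood at 424 ± 416 and 455 ± 440 CPM (n = 3 each; log2 −0.10 ± 0.85). The endothelial genes Cdh5 and Tek stood at 1847 ± 494 against 1968 ± 754 CPM and 732 ± 192 against 737 ± 134 CPM. The erythroid list rose, with 6 of 9 members higher, none past the threshold alone or adjusted over the list alone (camera adjusted p = 0.00716; adjusted p = 0.0873 with an estimated correlation). Its most abundant members were Slc25a37, higher by 0.42 ± 0.19 log2 in 3 of 3 pairs, and Tfrc, which differed by −0.14 ± 0.76. Lrp2 had 4.41 ± 1.36 against 4.99 ± 2.15 CPM (log2 −0.17 ± 0.61). Runx1 had 31.2 ± 1.60 against 42.1 ± 20.3 CPM, a difference of −0.43 ± 0.31 log2 that was 0.69 in replicate 1 and −0.74 ± 0.09 in replicates 2 and 3. The remaining fixed genes differed by −0.32 to 0.11 log2, with Gfi1 at −0.32 ± 0.55 and Itga2b at 0.11 ± 0.44 at the ends of this range.

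No gene passed the threshold with edgeR, with or without the replicate block, or with DESeq2, and 39 had an unadjusted p under 0.05. EdgeR called 75 genes in replicates 2 and 3, 69 higher and 6 lower, and 380 with the block, 233 higher and 147 lower. Across 9447 genes the differences of replicate 1 correlated with those of replicates 2 and 3 at −0.122 and −0.045, and those of replicates 2 and 3 with each other at 0.372. Genes named from this fit were chosen after their values were seen. Higher were Lrrtm2 (1.22 ± 0.26 log2, adjusted p = 0.0352), Casp4 (1.11 ± 0.24) and Ankle1 (1.01 ± 0.21). So were the imprinted non-coding RNA Meg3 (0.99 ± 0.13, adjusted p = 0.00103), Slc26a10 (0.95 ± 0.14) and the DNA glycosylase gene Neil3 (0.90 ± 0.11, adjusted p = 0.00073). Lower were Itgb3 (−0.89 ± 0.17), Pmp22 (−0.81 ± 0.13), Runx1 (adjusted p = 0.00073), Capn6 (−0.54 ± 0.09) and Rspo3 (−0.43 ± 0.08). In replicate 1 Casp4, Slc26a10 and Neil3 differed by −0.08, −0.07 and −0.20 log2, and Itgb3, Pmp22 and Capn6 by 0.59, 0.37 and 0.33. The same fit gave camera calls for the smooth muscle list, lower (adjusted p = 0.000548), the cell cycle list, higher (0.00113), the hypoxia list, lower (0.00309), and the early haematopoietic and endothelial lists, lower and higher (0.0222 and 0.0357). None of these passed in the fit of all replicates (0.0513, 0.566, 0.0854, 0.700 and 0.714). With an estimated correlation these calls of replicates 2 and 3 had adjusted p = 0.292 to 0.318. The erythroid list missed the threshold in replicates 2 and 3 (0.0997). With the replicate block the hypoxia list fell and the histone list rose (camera adjusted p = 0.0198 and 0.00329; adjusted p = 0.710 and 0.930 with an estimated correlation).

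The third HEI comparison set ENG−FDG+ against ENG+FDG− cells, which differ in both sort markers. Eng stood at 81.8 ± 68.6 against 455 ± 440 CPM (n = 3 each), lower in 3 of 3 pairs by −2.47 ± 0.89 log2 (adjusted p = 0.337, and 9.1e-05 with the replicate block). Slc7a8 rose by 3.73 ± 0.47 log2 in ENG−FDG+ cells (adjusted p = 0.0103), Actc1 by 3.84 ± 0.72 and Vgll3 by 3.72 ± 0.67 (adjusted p = 0.0453 each). Clec14a fell by 2.43 ± 0.39 log2 (adjusted p = 0.0278), the S100 family gene S100a16 by 3.64 ± 0.67 and the endothelial lectin gene Clec1a by 2.97 ± 0.57. Of the 6 fits without 1 library, Slc7a8 kept its call in 4, Actc1, Vgll3 and Clec14a in 1 each and S100a16 and Clec1a in 0. Actc1 ranged from 2.36 to 4.32 log2 and Vgll3 from 2.56 to 4.14 in them. Lrp2 was higher in 3 of 3 pairs, by 2.39 ± 0.63 log2 (adjusted p = 0.162, and 0.0114 with the block), or by 3.64 in replicate 1 and 1.51 ± 0.42 in replicates 2 and 3.

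The erythroid list rose in ENG−FDG+ cells, with 8 of 9 members higher, 1 past the threshold over all genes and 3 adjusted over the list alone. It kept its call (camera adjusted p = 3.9e-06) with an estimated correlation (adjusted p = 0.0101). The early haematopoietic (5.9e-07), megakaryocyte (3.9e-06), smooth muscle (3.9e-06), cell cycle (5.4e-05) and histone (0.0041) lists rose. The endothelial (2.1e-07), BMP and TGF-beta (3.3e-05) and Notch (0.0081) lists fell by camera adjusted p. In the same order their adjusted p = 0.0748, 0.122, 0.374, 0.195, 0.816, 0.195, 0.0748 and 0.330 with an estimated correlation. Over all genes 2 early haematopoietic, 1 megakaryocyte and 1 smooth muscle gene rose and 1 BMP and TGF-beta gene fell. Adjusted over the list alone, 6 early haematopoietic, 3 megakaryocyte, 5 smooth muscle, 1 histone and 1 Notch gene rose, 1 early haematopoietic, 2 endothelial, 4 BMP and TGF-beta and 2 Notch genes fell, and no cell cycle gene passed. The smooth muscle list missed the threshold in replicates 2 and 3 (camera adjusted p = 0.0633). The cell cycle median was −0.10 log2 in replicate 1 and 0.50 and 0.58 in replicates 2 and 3. EdgeR called 48 genes, 21 higher and 27 lower, with 1309 at an unadjusted p under 0.05. The count was 1757 with the block, 424 with DESeq2 and 3605 in replicates 2 and 3, and all 48 were called in each of these. The count was 2, 0 and 5 without ENG+FDG− replicates 1, 2 and 3, and 43, 15 and 0 without ENG−FDG+ replicates 1, 2 and 3. For any difference among the 3 HEI fractions edgeR called 44 genes, with 1043 at an unadjusted p under 0.05. The count was 1515 with the block, 434 with DESeq2 and 4002 in replicates 2 and 3. Leaving out 1 library gave 18, 10 and 8 genes for the ENG+FDG− replicates, 12, 9 and 9 for the ENG+FDG+ replicates, and 24, 19 and 5 for the ENG−FDG+ replicates, each in the order 1, 2 and 3. Fitting only the 2 groups compared, or only the 3 HEI groups, gave 0 genes for the ENG comparison, the third and any difference.

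The stage comparison set the 9 HEI against the 6 FLK1+ libraries, which also differ in reporter line and sort, and for which the culture days are not given, so the stage cannot be told apart from these. Endothelial genes rose in HEI cells, 24 up and 1 down of 25, and all 18 primitive streak genes tested fell. The endothelial gene that fell, named after its value was seen, was Etv2 (−3.35 ± 0.51 log2, adjusted p = 0.000205). Eng rose by 2.85 ± 0.62 log2 (adjusted p = 0.00268), Cdh5 by 5.65 ± 0.40 (adjusted p = 5.0e-07), Pecam1 by 5.09 ± 0.32, Tek by 4.61 ± 0.31 and Cd34 by 5.99 ± 0.42. Runx1 fell by 0.98 ± 0.20 log2 (adjusted p = 0.00153), with 132 ± 3.97 and 150 ± 10.9 CPM in the LacZ− and LacZ+ cells, 42.1 ± 20.3 and 31.2 ± 1.60 CPM in the ENG+FDG− and ENG+FDG+ cells and 273 ± 35.2 CPM in the ENG−FDG+ cells. Mixl1 fell from 644 ± 296 and 419 ± 160 CPM in LacZ− and LacZ+ cells to at most 1.22 ± 1.56 CPM in any HEI group.

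Fmo1, a flavin monooxygenase gene, rose by 7.88 ± 0.27 log2 (adjusted p = 6.0e-09) and Clec14a by 6.71 ± 0.35 (adjusted p = 5.2e-08). Tlr4, the receptor for bacterial lipopolysaccharide, had 0 counts in all LacZ− libraries, 1.06 ± 0.484 CPM in LacZ+ cells and 32.1 to 73.3 CPM in the means of the HEI groups. Emcn, Clec1a and the water channel gene Aqp1, all of the endothelium, had means of at most 0.367, 0.0618 and 0.259 CPM in FLK1+ cells. Their HEI means were 6.91 to 34.2, 3.01 to 24.6 and 10.3 to 34.8 CPM. In the other direction Mixl1 and Tdgf1 changed by −9.73 ± 0.79 and −9.37 ± 0.89 log2. Mesp1 and Fgf8, genes of the nascent mesoderm, had 0 counts in all 9 HEI libraries, which allows up to 3 counts each or 0.183 to 0.309 CPM, against 40.0 ± 54.0 and 13.6 ± 20.1 CPM in LacZ− cells. Lefty2, a Nodal antagonist, and Lhx1 had 17.3 ± 12.2 and 71.0 ± 64.3 CPM in LacZ− cells and at most 0.0605 and 0.149 CPM in the HEI groups. Among the other fixed genes Kit rose by 1.48 ± 0.21, Itga2b by 2.52 ± 0.32, Gfi1 by 2.28 ± 0.40 and Kdr by 0.62 ± 0.22 log2 (adjusted p = 0.0394, lost in 11 of the 15 fits without 1 library). Gata2, Tal1 and Lrp2 differed by 0.04 ± 0.28, 0.17 ± 0.30 and 0.34 ± 0.40 log2 and did not pass the test. Tal1 rose and Gata2 fell in replicates 2 and 3 (0.31 ± 0.06, adjusted p = 4.1e-05, and −0.18 ± 0.07, adjusted p = 0.0287).

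**Figure D3:**
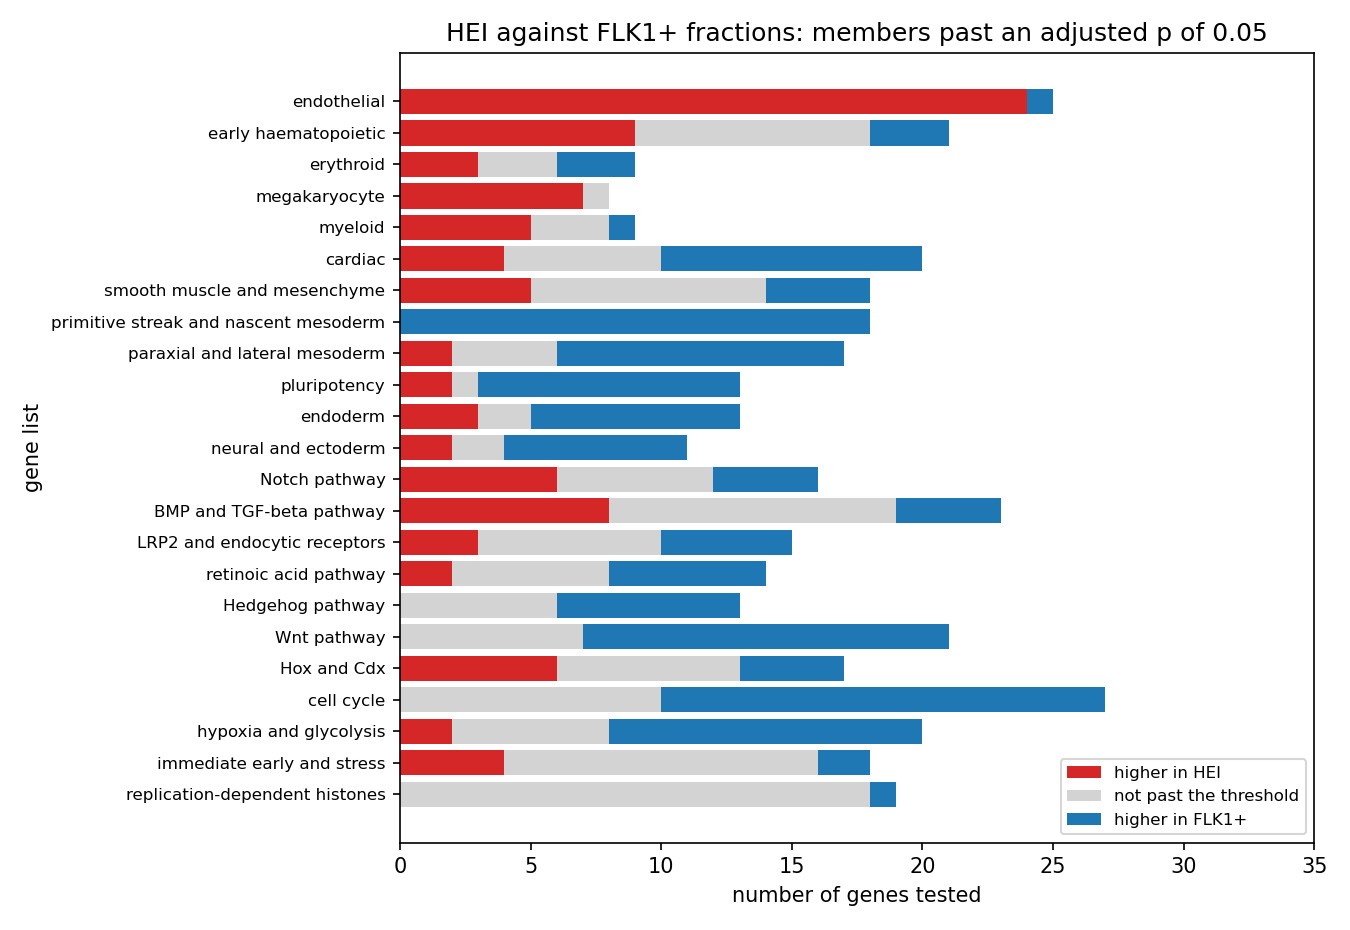
Number of tested members of each gene list that were higher in HEI cells, lower in HEI cells or not past the threshold, from the edgeR test of the HEI against the FLK1+ libraries. All 18 primitive streak genes were lower in HEI cells and 24 of the 25 endothelial genes were higher and 1 lower.

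Of the blood lists, early haematopoietic genes rose, 9 up and 3 down of 21 (camera adjusted p = 0.00731; adjusted p = 0.267 with an estimated correlation, and 0.0577 in replicates 2 and 3). Mecom stood at 4.38 ± 0.35, Meis1 at 3.38 ± 0.29, Vav1 at 2.53 ± 0.36 and Spn at −3.09 ± 0.43 log2. Megakaryocyte genes rose, 7 of 8 (camera adjusted p = 1.8e-05; adjusted p = 0.156 with an estimated correlation). They were led by Clec1b at 4.10 ± 0.85 log2. The endothelial and primitive streak lists had camera adjusted p = 3.7e-14 and 4.2e-14, and adjusted p = 0.111 and 0.0726 with an estimated correlation. Paraxial and lateral mesoderm genes fell, 11 down and 2 up of 17, among them Pdgfra, a growth factor receptor gene, at −4.08 ± 0.28 log2 (camera adjusted p = 0.0019; adjusted p = 0.215 with an estimated correlation, and 0.0508 with the replicate block). Pluripotency genes fell, 10 down and 2 up of 13 (camera adjusted p = 0.0019; adjusted p = 0.315 with an estimated correlation). Nanog and Pou5f1 stood at 15.1 ± 4.32 and 7.32 ± 4.24 CPM in LacZ− cells and at most 0.0331 and 0.0321 CPM in the HEI groups. Wnt pathway genes fell, 14 of 21, and kept this call with an estimated correlation (camera adjusted p = 2.9e-06 and 0.00549) but not with that and the replicate block (0.137). Among them were Wnt5b at −5.54 ± 0.46, Lgr5 at −4.78 ± 0.24 and the inhibitor Dkk1 at −4.55 ± 0.48 log2. Hedgehog genes fell, 7 of 13, including the transcription factor Gli2 at −4.95 ± 0.56 and the receptor Gas1 at −2.39 ± 0.20 (camera adjusted p = 0.00731; adjusted p = 0.252 with an estimated correlation). Cell cycle genes fell, 17 of 27 or 21 adjusted over the list alone, including Ccne1 at −2.04 ± 0.27 and Mcm7 at −1.17 ± 0.19 log2 (camera adjusted p = 0.000205; adjusted p = 0.215 with an estimated correlation). Hypoxia and glycolysis genes fell, 12 down and 2 up of 20, including Pfkl at −2.32 ± 0.37 and Bnip3 at −1.94 ± 0.39 log2 (camera adjusted p = 0.00593; adjusted p = 0.198 with an estimated correlation). For the endothelial, blood, streak, mesoderm, pluripotency, Wnt and hypoxia lists the counts adjusted over the list alone were the same as over all genes, and 8 Hedgehog genes fell that way. Notum, which encodes a Wnt deacylase, had 4.32 ± 0.609 and 4.23 ± 0.950 CPM in LacZ− and LacZ+ cells and at most 0.196 CPM in the HEI groups.

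No camera call was made for the cardiac (4 up and 10 down of 20, adjusted p = 0.115), endoderm (3 and 8 of 13, 0.0743), neural and ectoderm (2 and 7 of 11, 0.184), erythroid (3 and 3 of 9, 0.706) or myeloid (5 and 1 of 9, 0.0748) lists. None was made either for the smooth muscle (5 and 4 of 18, 0.706), Notch (6 and 4 of 16, 0.382), BMP and TGF-beta (8 and 4 of 23, 0.134), LRP2 and endocytic receptor (3 and 5 of 15, 0.803) or retinoic acid (2 and 6 of 14, 0.138) lists, or for the Hox and Cdx (6 and 4 of 17, 0.583), immediate early (4 and 2 of 18, 0.103) or histone (0 and 1 of 19, 0.263) lists. With the replicate block the immediate early list rose and the histone list fell (camera adjusted p = 0.00906 and 0.0223; adjusted p = 0.137 and 0.528 with an estimated correlation). Adjusted over the list alone 9 endoderm genes fell, 7 Notch genes rose and 4 LRP2 list genes rose, and the other counts of these lists were as over all genes. None of the 13 mitochondrially encoded genes was in the table. EdgeR called 5096 genes, 2317 higher and 2779 lower in HEI cells, with 6195 at an unadjusted p under 0.05. The count was 9039 with the block and 9815 in replicates 2 and 3, DESeq2 called 6059, and 5095 of the 5096 genes were called with the block.

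The difference between the reporter effects, HEI FDG+ against FDG− minus FLK1+ LacZ+ against LacZ−, was −0.73 ± 1.20 log2 for Eng and −1.31 ± 0.87 for Lrp2 (adjusted p = 1 each). No gene passed the threshold with edgeR, with or without the block, or with DESeq2, and 97 had an unadjusted p under 0.05. EdgeR called 4 genes in replicates 2 and 3, named after their values were seen. They were Cdh5 (−1.07 ± 0.15 log2, adjusted p = 0.0042), Runx1 (−0.96 ± 0.12, adjusted p = 0.00138), Capn6 (−0.96 ± 0.12) and the imprinted cell cycle inhibitor Cdkn1c (2.30 ± 0.39). With the block the same fit called 168, 56 higher and 112 lower.

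In the GENCODE M21 annotation of GRCm38, Eng lies on chromosome 2 from 32646595 to 32682669, Lrp2 on chromosome 2 from 69424340 to 69586065, and Runx1 on chromosome 16 from 92601466 to 92826149. Cdh5 lies on chromosome 8 from 104101625 to 104144511, and Slc7a8 on chromosome 14 from 54722209 to 54781946. The remaining genes are identified by their symbols as the table gives them.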

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

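The tests of a shared replicate 1 step, of counting noise, of other splits for the FLK1+ LacZ, HEI FDG and reporter-effect comparisons, and of blocked splits among the 3 HEI fractions were chosen only after the results were seen.

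For 6 gene lists the effect of reporter activity differed between HEI and FLK1+ cells by camera on the difference of the effects. The endothelial list (adjusted p = 4.22e-15, lower in HEI for 23 of 25 genes, median log2 −1.32), the early haematopoietic list (adjusted p = 4.99e-07, lower for 20 of 21, median −0.72) and the megakaryocyte list (adjusted p = 0.000314, lower for 8 of 8, median −0.84) had lower log2 effects in HEI cells. So had the myeloid list (adjusted p = 0.0119, lower for 7 of 9, median −1.14) and the Hox and Cdx list (adjusted p = 0.038, lower for 15 of 17, median −0.46). The primitive streak list, which fell in FLK1+ LacZ+ cells, had a higher one (adjusted p = 0.0119, higher for 12 of 18, median 0.14). The HEI FDG median of the streak list was 0 log2 in each replicate, and Mesp1 and Fgf8 had 0 counts in all HEI libraries. Its difference thus mostly repeats the fall in FLK1+ cells and says little about the reporter in HEI cells. In the fit of all libraries the lists with lower effects had HEI FDG medians of −0.069 to 0.035 log2. Their FLK1+ LacZ medians were 0.33 to 1.255. Their differences thus mostly repeat the rises in FLK1+ cells as well. None of the 6 lists kept the call with an estimated correlation (adjusted p = 0.141, 0.141, 0.355, 0.441, 0.441 and 0.595 in this order). With the replicate block the Hox and Cdx list lost it (0.112), and the hypoxia and histone lists gained it (0.0434 and 0.0093), but none of the 8 lists passed with that and an estimated correlation (0.134 to 0.679). In replicates 2 and 3 the endothelial, early haematopoietic, primitive streak and smooth muscle lists passed (0.00143, 0.000234, 0.027 and 0.000164), of which the last was lower in HEI cells and had not passed in all replicates (0.0628). The medians of that fit were −0.24, −0.29, 0.41 and −0.80, against −0.31 for the megakaryocyte, −0.29 for the myeloid and −0.50 for the Hox and Cdx list. None of the 4 lists that passed did so with an estimated correlation (0.307, 0.307, 0.330 and 0.307), and the megakaryocyte, myeloid and Hox and Cdx lists did not (0.072, 0.0551 and 0.0551). The 2 stages also differ in reporter line and sort, so none of this can be assigned to stage. The lines left out because a date stood in place of a gene symbol held 486356 reads, 0.153% to 0.349% of each library, more than a count of 0 allows.

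The replicate 1 libraries stood apart from replicates 2 and 3 in every group. Their difference was shared between FLK1+ and HEI groups, with a median correlation across genes of 0.865 (0.746 to 0.890). Cells further along or behind in differentiation were argued against as the main source, because the correlation with the stage difference was 0.048 in FLK1+ and 0.017 in HEI cells. A shift in fewer genes beneath the shared difference could not be seen by this correlation and stays open. A smooth fit on GC content and transcript length removed 63.2% of the variance, so a step of amplification or library preparation that acts on these is a candidate explanation. The labels name no batch. As titles the replicate 1 libraries carry the numbers 23 and 24 (FLK1+) and 110 to 112 (HEI). Those of replicates 2 and 3 carry 249 to 258, and what these numbers stand for is not given. No biological explanation other than the stage of differentiation was tested.

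The FLK1+ LacZ difference was wider in replicate 1. Counting noise was argued against, since 23 endothelial genes with at least 100 reads had a median of 2.04 log2 in replicate 1 and 0.32 in replicates 2 and 3, a gap of 1.71. A sharper separation of the same populations was argued against as the whole cause, since the median of 35 streak and mesoderm genes was −0.35 in replicate 1 and −0.53 in replicates 2 and 3, a gap of 0.177 in the direction opposite to the one it needs. A different mix of cells in replicate 1 stays open, since the pluripotency list had medians of 1.22 in replicate 1 and −0.043 and −0.108 in replicates 2 and 3, and the endoderm list 0.736, 0.141 and 0.074. A biological difference between the cultures was not tested and stays open as well.

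Transcripts retained in the nucleus were higher in ENG+FDG+ than in ENG+FDG− HEI cells of replicates 2 and 3, by a median of 0.26 and 0.38 log2 over 31 transcripts, 28 of them higher, in a list written after the values of Malat1, Meg3 and Clk1 had been seen. A trend with length or GC content was argued against, as 99% of the median was left after a smooth fit (0.319 of 0.323). Handling shared by all reporter-positive sorts and a difference tied to the reporter in every replicate cannot be told apart. The median was 0.103 in FLK1+ LacZ+ against LacZ− cells and 0.176 in replicate 1, and each lay between the bounds set for and against. All listed transcripts but Clk4, Rbm39, Rbm5, Son and Mdm4 were higher in the ENG+FDG+ cells of replicate 1 as well.

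For the 3-against-3 comparisons the 10 splits are too few for a share under 0.05. The real split and the highest other one called 0 and 0 genes for FLK1+ LacZ, 0 and 0 for HEI FDG, 38 and 0 for HEI ENG and 48 and 0 for the third HEI comparison. In the same order 10, 10, 1 and 1 of the 10 splits called as many as the real one. With the replicate block, over the 4 splits that part all pairs, the last comparisons gave 1705 and 0 and 1757 and 0. For any difference among the 3 HEI fractions 9 of 100 splits called at least the real 44, a share not under 0.05. The highest called 4475, and the 4 splits with all replicate 1 libraries in 1 group called at least 3385, which points to the structure of the samples. Of the 34 splits with 1 replicate 1 library per group, the real one included, 3 called as many. With the block, 2 of the 36 splits that have 1 library of each replicate number in every group called at least the real 1515, the other calling 1626. The 4 splits, the real one included, that keep the ENG−FDG+ libraries together called at least 1336, and the other 32 called 0. Such splits keep the ENG− difference, as those with all replicate 1 libraries in 1 group keep the replicate 1 difference. The shares of 9 of 100 and 2 of 36 count such splits, so neither can decide about chance. For HEI against FLK1+ 2 of 100 splits, the real one included, called as many as the real 5096, a share under 0.05. The other called 5322 and put the 5 replicate 1 libraries on 1 side, as did 3 splits that called 0. The drawn splits mix FLK1+ and HEI libraries within groups. They thus speak only against the absence of any difference between the libraries. The blocked count was 9039. For the difference of reporter effects the real count was 0, which all 100 splits reach by definition, so they say nothing about chance. The highest called 2632, and its cause was not tested.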

How the results depend on the processing

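The fits of replicates 2 and 3, with and without the block, were chosen only after the data were seen, and the other alternatives were planned.

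Counts of genes depended on the replicate number as a block and, in more comparisons, on leaving out replicate 1. With the block edgeR called 1705 genes for HEI ENG against 38, 1757 for the third HEI comparison against 48, 1515 among the 3 HEI fractions against 44 and 9039 for HEI against FLK1+ against 5096, and 0 as before for FLK1+ LacZ, HEI FDG and the difference of reporter effects. All 38, 48 and 44 genes were among those called with the block, and the block removes the spread between replicate 1 and the others that the unblocked fit counts as error. Among lists it ended the myeloid call of the ENG comparison (camera adjusted p = 0.113), the paraxial call of the stage comparison (0.0508) and the Hox and Cdx call of the reporter effects (0.112), and added the calls given beside each comparison. The block changed no other list call, and no call of a named gene was lost with it.

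In replicates 2 and 3 edgeR called 8 genes for FLK1+ LacZ, 75 for HEI FDG, 3899 for HEI ENG, 3605 for the third comparison, 4002 among the fractions, 9815 for the stage and 4 for the reporter effects. With the block these became 157, 380, 4646, 4369, 5052, 9883 and 168. Whether replicates 2 and 3 are separate cultures is not given, so these counts may not reflect the spread between cultures. DESeq2 called 7, 405, 424 and 434 for FLK1+ LacZ, HEI ENG, the third comparison and the fractions. Without a filter on low counts the last 3 gave 12, 13 and 19 genes, with at least 5 CPM in 3 libraries HEI ENG gave 65, and against a fold of 1.5 HEI ENG gave 4, the third comparison 3 and the stage 2902. With only the groups compared HEI ENG, the third comparison and the fractions gave 0, a fit with fewer libraries to estimate the spread. RLE scaling gave 52, 52, 45 and 5047 for HEI ENG, the third comparison, the fractions and the stage. For the other changes the cause was not tested.

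Leaving out 1 library gave 0 to 1 genes for FLK1+ LacZ, 0 to 34 for HEI ENG, 0 to 43 for the third comparison, 5 to 24 among the fractions, 4656 to 5732 for the stage and 0 for HEI FDG and the reporter effects. Each such fit leaves a group with 2 libraries and pools the spread over all groups.

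Of the named genes, 25 values changed sign outside the fits without 1 library, 4 of them past the threshold on either side, and the cause was not tested. In FLK1+ LacZ cells of replicates 2 and 3, without and with the block, Eng was −0.053 and −0.052 log2, Gfi1 −0.363 and −0.361 and Gata2 −0.035 and −0.034. In the HEI FDG comparison Kdr was 0.002 without a filter, 0.016 with at least 5 CPM, 0.008 with only the groups compared and 0.109 in replicates 2 and 3 with or without the block. Tek there was 0.011 with at least 5 CPM, 0.003 with only the groups compared and 0.074 and 0.073 in replicates 2 and 3 without and with the block, where Pecam1 was 0.001 and Cdh5 0.054 in both. Itgb3 in the HEI FDG comparison was −0.351 with the block and −0.891 and −0.897 in replicates 2 and 3, the last 2 past the threshold. Gata2 in the stage comparison was −0.047 with the block and −0.18 and −0.184 in replicates 2 and 3, again the last 2 past it.

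Fits without 1 library changed the sign of 65 values, none past the threshold. In FLK1+ LacZ the ranges were −0.338 to 0.957 log2 for Eng, −0.386 to 0.146 for Kdr, −0.046 to 0.363 for Gata2, −0.032 to 0.606 for Tal1, −0.03 to 0.328 for Hand1 and −0.243 to 0.382 for Rspo3. In HEI FDG they were −1.31 to 1.074 for Eng, −0.088 to 0.116 for Kdr, −0.382 to 0.232 for Lrp2, −0.172 to 0.188 for Tek, and −0.138 to 0.317 for Kit. Further ranges were −0.272 to 0.546 for Itga2b, −0.274 to 0.113 for Pecam1, −0.332 to 0.267 for Cdh5, −0.743 to 0.115 for Gfi1, −0.569 to 0.214 for Gata2, −0.451 to 0.017 for Tal1, −0.555 to 0.251 for Tfrc and −1.585 to 0.804 for Itgb3. In HEI ENG they were −1.011 to 0.166 for Gata2, −0.012 to 0.108 for Slc25a37, −0.091 to 1.598 for Notch1, −0.457 to 0.218 for Top2a, −0.283 to 0.091 for Mki67, −5.921 to 1.085 for Hba-x, −4.456 to 0.251 for Hbb-y, −6.103 to 0.683 for Twist2, −1.838 to 0.355 for Hist1h1b and −1.888 to 0.807 for Hist1h1e. In the stage comparison they were −0.15 to 0.183 for Gata2, −0.01 to 0.31 for Tal1 and −2.258 to 0.428 for Hist1h3c, and for the reporter effects −1.933 to 0.451 for Eng.

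Of the gene lists, 51 values changed direction, none past the threshold on either side, and the adjusted p values of the changed direction follow. In FLK1+ LacZ with the block they were 0.729 for BMP and TGF-beta and 0.861 for immediate early. For replicates 2 and 3 they were 0.719 for erythroid, LRP2 and Hedgehog, 0.453 for cardiac, pluripotency and Notch, 0.786 for BMP and TGF-beta, 0.538 for hypoxia and 0.650 for immediate early, which gave 0.986 with fry and 0.978 with RLE scaling. In HEI FDG with the block they were 0.971 for megakaryocyte and 0.876 for primitive streak, LRP2 and Hox, and in replicates 2 and 3 0.829 for primitive streak and 0.875 for Notch, LRP2 and immediate early. In HEI ENG with the block they were 0.667 for paraxial, pluripotency and retinoic acid and 0.690 for Hox. Within replicates 2 and 3 they were 0.959 for paraxial, 0.602 for pluripotency, 0.910 for neural, 0.522 for retinoic acid and 0.974 for Hedgehog and Hox, and 0.941 with fry for retinoic acid. In the third comparison with the block they were 0.856 for pluripotency and 0.741 for Hox, in replicates 2 and 3 0.80 for endoderm and hypoxia, 0.928 for neural, 0.711 for Hedgehog and 0.385 for Hox, and 0.919 with fry for Hedgehog. In the stage comparison they were 0.985 for erythroid and 0.432 for smooth muscle in replicates 2 and 3, and 0.451 for LRP2 and 0.673 for Hox with fry. For the reporter effects they were 0.0825 for pluripotency, 0.467 for Notch and Wnt, 0.765 for LRP2 and 0.181 for Hedgehog in replicates 2 and 3, and 0.986 and 0.999 for Hedgehog with fry and RLE scaling.

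An estimated correlation ended 38 list calls and left 100 list results on their side of the threshold. With the block as well, only the primitive streak list of FLK1+ LacZ (0.0311), the BMP and TGF-beta list of HEI ENG (0.0388) and, in the third comparison, the erythroid (0.034) and BMP and TGF-beta (0.0269) lists passed. Fry ended 24 list calls and added 9. It ended all calls for FLK1+ LacZ (0.291 to 0.986), HEI FDG (0.383) and the reporter effects (0.984). For HEI ENG it ended the endothelial (0.0977), myeloid (0.416), smooth muscle (0.159), Notch (0.262) and cell cycle (0.117) calls, and for the third comparison the endothelial (0.0848), smooth muscle (0.274), Notch (0.189), cell cycle (0.067) and histone (0.786) calls. Fry added Wnt, lower in HEI ENG (0.0185) and higher in the third comparison (0.0184). In the stage comparison it added the erythroid, myeloid, cardiac, endoderm, neural, BMP and TGF-beta and retinoic acid lists (9.56e-06 to 0.00415). Fry asks whether a list moves and camera whether it moves more than other genes. Depth was 9705729 counts or more per library, which leaves genes near 0 counts, such as Mesp1 and Fgf8 in HEI cells, limited by counting.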

Other observations

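The test of imprinted genes against random lists was chosen only after the result was seen, and the list was written after 5 of its genes (Grb10, Cdkn1c, Igf2r, Mest and H19) had been seen to differ.

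Imprinted genes were frequent among the genes that differed between LacZ+ and LacZ− FLK1+ cells in replicates 2 and 3 with the replicate block. Of 56 tested, 8 were called, against a median of 1 and at most 7 in 10000 random lists matched on expression, so 100% of the lists had fewer. The result rests on this fit, since without the block only 2 were called, Grb10 and Cdkn1c, both seen before, and the other 6 had adjusted p = 0.0831 to 0.794. Without the 5 genes seen before, 3 of 51 were called, more than in 96.6% of matched lists. That count included Airn, whose reads cannot be separated without strand from Igf2r, a gene seen before, and without Airn 2 of 50 were called, more than in 84.4% of lists. In replicate 1, 87.5% (7 of 8) had the same sign, Airn being the exception. Grb10 differed by −1.71 log2, Cdkn1c by −2.09, Igf2r by −0.67, Phlda2 by −0.61, H19 by 0.45, Igf2 by 0.43, Mest by 0.46 and Airn by 0.82. The genes not seen before thus do not show that imprinted genes differed more often than others between the sorted fractions.

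Hprt, a purine salvage gene on the X chromosome, had 83 and 270 counts in the FLK1+ libraries of replicate 1 against 728 to 987 in replicates 2 and 3, and 68, 106 and 17 counts in the HEI libraries of replicate 1 against 140 to 342. Lrp2 reached its highest level, 45.1 CPM, in ENG−FDG+ replicate 1 and its next highest, 22.1 CPM, in ENG−FDG+ replicate 3, followed by 19.2 CPM in FLK1+ LacZ+ replicate 1.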
